A study of Mus musculus with 4 samples.

How the data were processed

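The data are 4 single-cell RNA libraries, 1 for each combination of tissue (aorta or left lung lobe) and Oct4 genotype in endothelial cells (wild-type or knockout), from female Apoe-deficient mice of an endothelial lineage tracing line fed a Western diet for 5 weeks. Per the labels' protocols, tissue from 2 wild-type and 3 knockout mice was digested in buffers with 1 µg/mL actinomycin D, which blocks transcription, eYFP-positive cells were sorted with littermates lacking the Cdh5 driver setting the gate, and cells were captured with the 10x Chromium system, barcoded and sequenced. The deposited values are whole-number UMI counts per gene and cell, made by the authors with Cell Ranger on mm10, per the submitters' processing notes; the versions are not given in the sources used here. Each matrix had 31053 rows. The aortic matrices name genes by symbol and the lung matrices by Ensembl identifier, of which 30934 matched the GENCODE M21 annotation and 119 did not; the annotation used for counting is not given in the sources used here. Rows of the same symbol were summed (36 rows in the aorta, 28 in the lung). Coordinates are those of GENCODE M21 on mm10, 1-based, for the whole gene; counts are per gene, so exons and UTRs were not separated.

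Depth was 1034161, 4483756, 1506574 and 1052504 UMIs in the wild-type aorta, knockout aorta, wild-type lung and knockout lung. Barcodes with fewer than 500 UMIs, fewer than 200 genes or more than 15% mitochondrial UMIs were left out: 50, 57, 27 and 26. Scrublet, run per library in scanpy at an assumed rate of 0.8% per 1000 barcodes, called 3, 5, 9 and 9 doublets (0.752%, 0.319%, 1.16% and 1.79%), which were removed. Median mitochondrial shares of kept cells were 4.41%, 3.96%, 2.89% and 2.96%. No correction for free RNA was made.

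Cells were clustered within each tissue with both genotypes together, on log-transformed counts scaled to 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster was named after the class with at least 3 markers among its 10 leading genes against all other cells, or else after the class whose 5 most detected markers had the highest mean detection. It stayed unnamed with fewer than 3 markers detected in at least 25% of its cells, or if its leading genes against cells of other classes held more markers of another class than of its own. Against cells of other classes no endothelial-like cluster was led by markers of another class. Against all other cells aortic clusters 1 and 7 were, with Krt18 and Mfap5 and no marker of their own, so values without both, and per cluster, are given as well. No annotation of cell types by the authors was used here, and names rebuilt from markers can differ from theirs.

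UMIs of endothelial-like cells were summed per library and divided by the library's sum to give CPM. CPM have exact Poisson 95% intervals, ratios exact conditional 95% intervals and shares exact Clopper-Pearson 95% intervals; all cover counting error only, since each group is 1 library pooled from several mice. A count of 0 was given a limit of 3 counts, per library. Genes entered a comparison with a mean of at least 50 CPM and at least 30 UMIs in both libraries together. Genes at least 2-fold apart were counted as a description of size. For 29 gene lists and 19 lists of cell type markers, the median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins, where at least 3 members were measured. Clusters with at least 20 cells in both libraries, 7 in the aorta and 5 in the lung, were compared one by one. Values with clusters weighted alike used only these clusters, so aortic clusters 2 and 8 were left out of them. No test, p-value or standard error was computed across cells.

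The named genes follow a rule: ranked by the interval bound nearest to 1, the 12 highest and 12 lowest per tissue (the 8 highest and 8 lowest between tissues), leaving out mitochondrially encoded, ribosomal protein, haemoglobin and unnamed genes and non-endothelial markers; the 2 highest and 2 lowest members of each list; and Pou5f1, Abcg2, Hmox1, Klf4 and Klf2. Groups, filters, comparisons, lists, markers, this rule and most alternatives were fixed before the data were examined. List members are named only for lists outside the random range and for inflammatory activation and endothelial-to-mesenchymal transition, and alternatives were recomputed for these named genes only; this narrowing was chosen after all values had been seen, to shorten the account. A few other genes are named as chosen after their values were seen, and some genes that the rule picks are not reported here.

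The share of 3' sequence shared with other genes is the percent of 50-mers in the last 300 bases of a gene's GENCODE M21 transcripts that also occur in transcripts of another gene. It could be computed for 3797 of 3812 genes, and 96 shared at least 50%. Such counts can lose or gain reads to near-identical copies.

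The procedure was tested on simulated counts drawn by Poisson sampling from the mean level of both libraries and their real sizes, which holds no variation between mice, with 200 genes changed by known folds. For the aortic comparison, on 2966 genes, the interval covered the true ratio for 95.0% of 2766 unchanged genes and none of these was called 2-fold apart. It excluded 1 in the right direction for 92.7% of 68 genes changed 1.5-fold, 98.5% of 66 changed 2-fold and 100% of 66 changed 4-fold, and 1, 38 and 66 of them passed 2-fold; their true ratio was covered for 97.1%, 95.5% and 87.9%. For the lung comparison, on 3344 genes, the interval covered 96.1% of 3145 unchanged genes, the same shares were 82.1% of 67, 98.5% of 66 and 100% of 66, and 2, 39 and 66 passed 2-fold, with coverage of 98.5%, 92.4% and 97.0%. Of 200 simulated lists of 15 unchanged genes, 5% in the aorta and 3% in the lung lay outside the random range, and 100% of lists changed 1.5-fold upwards lay above it. The shared-sequence step returned the known share in all 200 made-up genes, after a chance base match in a first version of this check was corrected.

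Alternatives were other scalings (TMM factors from edgeR 4.0.16 in R 4.3.3, or CPM without mitochondrial and ribosomal protein genes), all kept cells, a gate of 8 endothelial markers in place of clusters, the mean of per-cell CPM, clusters weighted alike, cells thinned to equal depth (1186 UMIs in the aorta, leaving out 86 of 352 wild-type and 168 of 1327 knockout cells, and 1087 UMIs in the lung, leaving out 155 of 687 and 113 of 451), no cell filter or a stricter one (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, joint clustering of all libraries, and mean CPM filters of 20, 100 or none. Added after seeing the data were sums without clusters 1 and 7, with lymphatic-like cells, without clusters led by immediate early genes (4 and 9 in the aorta, 1 in the lung), without clusters under 20 cells, without each gene's highest cell and without genes of shared 3' sequence. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.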

Results

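Single-cell gene expression was measured in endothelial cells sorted from the aorta and from the left lung lobe of female mice of a line described by the submitters as lacking Apoe, the apolipoprotein that clears lipoprotein remnants, after 5 weeks of Western diet. The mice carried either an intact Oct4 gene (official symbol Pou5f1, a transcription factor of pluripotent cells) or a deletion of it in endothelial cells, and the endothelial lineage was traced by eYFP. Per the labels, 2 wild-type and 3 knockout mice were used, and each combination of tissue and genotype gave 1 droplet library. There were 4 libraries with 1 library per group, so no difference has a replicate check, no test was run, and every interval covers counting error only. The deposited matrices held 449 barcodes and 1034161 UMIs in the wild-type aorta, 1623 barcodes and 4483756 UMIs in the knockout aorta, 800 barcodes and 1506574 UMIs in the wild-type lung, and 529 barcodes and 1052504 UMIs in the knockout lung. After filtering, 396, 1561, 764 and 494 cells remained in the same order, with medians of 2074, 2325, 1642 and 1704 UMIs and 1046, 1183, 930 and 948 genes per cell.

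Pou5f1 transcripts were at or under the limit that a count of 0 allows in every library. The gene lies on chromosome 17 between 35506018 and 35510772 (mm10, GENCODE M21). The deposited barcodes held 0 UMIs of it in the wild-type aorta, 1 in the knockout aorta, 2 in the wild-type lung and 1 in the knockout lung. Among endothelial-like cells, none of 352 in the wild-type aorta held a UMI, which allows a share of cells with a UMI of up to 1.04% (exact 95% interval), and the knockout aorta stood at 0.262 CPM (counts scaled by the UMI sum of the library). In the wild-type and knockout lung the levels were 0.774 and 1.15 CPM, against limits of 2.32 and 3.46 CPM that 3 counts would give. No ratio was therefore taken, and a tag at the 3' end does not check whether an internal part of the gene was deleted.

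Most sorted cells were endothelial-like in every library. Their share was 88.9% of kept cells in the wild-type aorta (exact 95% interval 85.4 to 91.8), 85.0% in the knockout aorta (83.1 to 86.8), 89.9% in the wild-type lung (87.6 to 92.0) and 91.3% in the knockout lung (88.5 to 93.6). Lymphatic endothelial-like cells, led by Ccl21a and Mmrn1, numbered 40 and 192 in the wild-type and knockout aorta and 42 and 18 in the lung. As shares of kept cells these were 10.1% (7.3 to 13.5) and 12.3% (10.7 to 14.0) in the aorta. In the lung they were 5.5% (4.0 to 7.4) and 3.6% (2.2 to 5.7), so the intervals overlapped in each tissue. Smooth muscle-like cells numbered 2 and 17 in the aorta (0.51% and 1.09%). Macrophage-like cells numbered 2 and 25 in the aorta (0.51% and 1.60%) and 23 and 24 in the lung (3.0% and 4.9%). Fibroblast-like cells numbered 12 and 1 in the lung. The lung macrophage-like cluster was led by the airway gene Scgb1a1, ahead of Lyz2 and Tyrobp, and had a median of 973 UMIs. Its 5 most detected macrophage markers had a mean detection of 28.9%, so this name is uncertain. The eYFP gate sets these shares, and the classes were rebuilt from marker genes. The comparisons below sum the UMIs of endothelial-like cells, 862960 from 352 wild-type and 3815705 from 1327 knockout cells in the aorta, and 1291642 from 687 and 865809 from 451 cells in the lung.

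Aortic endothelial-like cells of the knockout library held more transcripts of genes that present antigen, and fewer of Serinc3 and Lpl. H2-Q7, a nonclassical MHC class I gene (chromosome 17, 35439155 to 35443773), stood at 385 CPM in the knockout and 137 CPM in the wild-type library, 2.82-fold higher (95% interval 2.33 to 3.43) and higher in all 7 clusters that could be compared (3.54-fold without the highest cell of each library). Serinc3, a membrane protein that brings serine into lipids, was 2.01-fold lower (1.88 to 2.15), at 747 against 1502 CPM, and lower in all 7 clusters. Lpl, the lipoprotein lipase that frees fatty acids from triglyceride, was 3.10-fold lower (2.53 to 3.78) but went both ways between clusters, lower in 3 and higher in 2 of 5. Of 2973 genes with enough counts, 13 were at least 2-fold higher and 27 at least 2-fold lower in the knockout library, while 94.1% lay within 1.5-fold.

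The 12 genes ranked highest in the aorta had varied roles. Serping1, the inhibitor of complement C1, was 2.34-fold higher (1.68 to 3.34), and Tmem176a stood at 201 against 102 CPM, both higher in 7 of 7 clusters. Lgmn, a lysosomal protease, stood at 476 against 242 CPM and was higher in 6 of 7 clusters. Igfbp4, a binding protein of insulin-like growth factors, stood at 304 against 151 CPM, higher in 4 and lower in 3 of 7 clusters. H2-Q6, a neighbour of H2-Q7 with 49.4% of its 3' sequence shared with other genes, was 2.72-fold higher. Lcn2, an iron-siderophore binding protein of the acute phase, stood at 250 CPM against 2.32 CPM, which is 2 UMIs. In the knockout library 27.3% of its UMIs came from 1 cell, and the ratio was 156.7 without the highest cell of each library. Most of its knockout UMIs lay in clusters 8 (612 UMIs in 29 of 123 cells) and 4 (293 UMIs in 16 of 159 cells). Over 18 alternatives its log2 ratio ranged from 0.99 to 7.49. Col8a1, a short-chain collagen of the vessel wall, the transcription factor Sox4 and Emcn, an endothelial sialomucin, were 2.17-, 2.54- and 1.78-fold higher. These 3 genes lead clusters 8 and 2, which hold 123 and 114 knockout cells, 7.9% and 7.3% of those kept. Of the wild-type cells they hold 10 and 8, 2.5% and 2.0% of those kept. With clusters weighted alike their log2 ratios were 0.23, 0.32 and 0.28. That setting leaves clusters 8 and 2 out, so it does not show how the libraries compare within them.

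Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652), stood at 404 CPM in the knockout and 148 CPM in the wild-type aorta. In the wild-type library 91.4% of its UMIs came from 1 cell. Without the highest cell of each library the gene was 22.8-fold higher in the knockout. Its log2 ratio was 0.18 without the clusters led by immediate early genes, and its ratio 1.92 without cells holding UMIs of leukocyte genes. Both of these settings keep that wild-type cell, which lies in cluster 8. In the other endothelial-like clusters Cd74 was higher in the knockout library, though not always beyond the intervals. H2-Aa and H2-Ab1, which encode the class II chains, were 1.97- and 1.65-fold higher, with 94.7% and 81.2% of the wild-type UMIs in 1 cell. Without the highest cells these folds were 25.6 and 6.28. For Cd74, H2-Aa and H2-Ab1 such folds rest on the few wild-type UMIs left and have no interval, so their size is uncertain. Cd74 UMIs were found in 257 of 1327 knockout and 10 of 352 wild-type cells.

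The 12 genes ranked lowest in the aorta included Lpl and Serinc3. Gpihbp1, which carries lipoprotein lipase across capillary endothelium, stood at 189 against 374 CPM, and Rgcc, a regulator of the cell cycle, at 98.5 against 249 CPM. Lpl, Gpihbp1 and Rgcc lead cluster 3, a capillary-like group with 6.66% of the knockout and 14.9% of the wild-type kept cells (104 and 59 cells). With clusters weighted alike the log2 ratios of Lpl, Gpihbp1 and Rgcc were -0.81, -0.02 and -0.35; within clusters Rgcc was higher in 3 of 4 and Gpihbp1 in 2 of 4. Tomm6, of the outer mitochondrial translocase, was 2.40-fold lower and Gstp1, a glutathione transferase, 2.35-fold lower, both in 7 of 7 clusters. Nme2, a nucleoside diphosphate kinase, stood at 53.7 against 136 CPM and Plac9b at 59.0 against 205 CPM. Tomm6, Gstp1, Nme2 and Plac9b share 64.9%, 53.0%, 98.0% and 100% of their 3' sequence with other genes, so their counts are uncertain. Ctgf, a matricellular protein that leads cluster 1, stood at 109 against 256 CPM. The chemokines Ccl5 and Cxcl9 also ranked lowest, but all 95 wild-type UMIs of Ccl5 and 72.2% of those of Cxcl9 came from 1 cell, and Cxcl9 had a ratio of 0.417 without the highest cells.

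**Figure D1:**
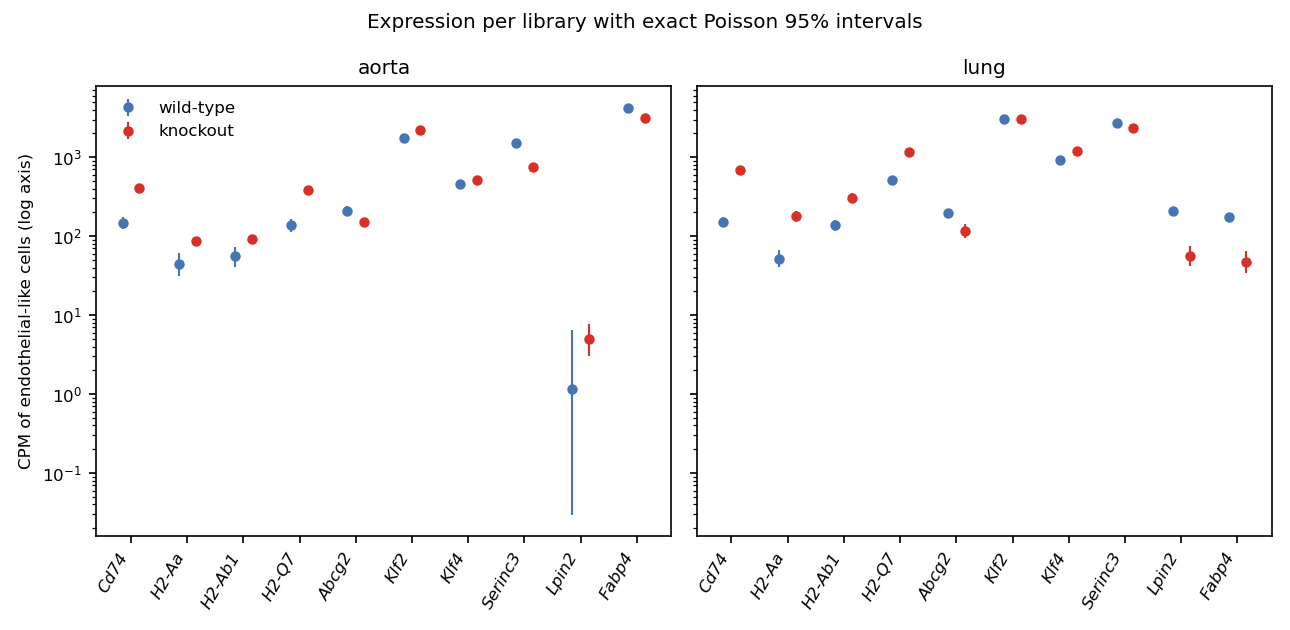
CPM of 10 genes (log axis) in the summed endothelial-like cells of each library, wild-type in blue and knockout in red, with bars for exact Poisson 95% intervals. H2-Q7 stood at 137 and 385 CPM in the wild-type and knockout aorta and at 521 and 1169 CPM in the lung, while Lpin2 differed at 208 and 56.6 CPM in the lung; 91.4% of the wild-type aortic UMIs of Cd74 come from 1 cell.

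Of the 29 gene lists, 27 had at least 3 measured members in the aorta, and 9 of their median log2 ratios lay outside the middle 95% of medians of 10000 random lists matched on expression. The MHC class II list had a median of 0.98 (percentile 99.99) with all 3 measured members higher. It was -0.24 (11.7) without the clusters led by immediate early genes, with H2-Aa and H2-Ab1 at log2 ratios of -0.24 and -0.34. That setting keeps cluster 8, where 1 wild-type cell held all 117 Cd74 UMIs of the cluster. Most wild-type UMIs of H2-Aa and H2-Ab1 also came from 1 cell. In the MHC class I and antigen processing list the median was 0.18 (98.3) with 11 of 13 higher; H2-T22 and H2-T23 went the other way, H2-T23 at 85.2 against 147 CPM and lower in 7 of 7 clusters. The interferon response list had a median of 0.25 (99.6), but -0.060 with a mean CPM of at least 100. Its 10 members split, with Gbp7, a guanylate-binding GTPase, at 72.9 against 42.9 CPM and Ifi27l2a 1.57-fold higher, but Ifit1 and Isg15 at ratios of 0.522 and 0.598. The venous list had a median of 0.23 (99.4) with 6 of 10 members higher, but -0.013 with clusters weighted alike and -0.095 with a mean CPM of at least 20. Vcam1, an adhesion molecule for leukocytes, was 1.55-fold higher at 2007 against 1294 CPM and the platelet and leukocyte adhesion molecule Selp 1.60-fold higher (lower in 4 of 6 clusters, and a log2 ratio of -0.19 with clusters weighted alike), while Ephb4 and Ptgs1 had ratios of 0.765 and 0.889; Selp leads cluster 8.

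Lists below the random range in the aorta concerned lipids, matrix, mitochondrial transcripts and immediate early genes. The lipid efflux and ABC transporter list had a median of -0.35 (percentile 0.26) with 4 of 6 members lower: Mylip, which marks the LDL receptor for degradation, at 105 against 152 CPM, and the HDL receptor Scarb1 at a ratio of 0.705 (a log2 ratio of 0.027 with the stricter cell filter), beside Abca1 (lower in 6 of 7 clusters, and a log2 ratio of -0.49 at equal depth) and Apoe at 1.01 and 1.00. Apoe transcripts were present (66 and 292 UMIs), and a 3' tag does not check that knockout allele. Abcg2, a transporter of the same list, had a ratio of 0.715 (0.604 to 0.849) and was lower in 6 of 7 clusters; it is among the genes that lead cluster 5. The fatty acid list had a median of -0.14 (1.82), but -0.039 (19.5) with clusters weighted alike. Of its 16 members 12 were lower, among them Lpl and Gpihbp1, which lead cluster 3, while Fabp5, a fatty acid carrier, and Etfa had ratios of 1.47 and 1.18. The extracellular matrix list had a median of -0.16 (0.11) with 12 of 19 lower, among them Ltbp4, which binds latent TGF-beta, at 1107 against 1685 CPM and the laminin chain Lamb2 at a ratio of 0.730, but Col5a2 at 1.48. Mitochondrially encoded transcripts had a median of -0.13 (1.55) with 11 of 12 lower. Here mt-Atp8 stood at 114 against 236 CPM and mt-Nd2 had a ratio of 0.792, while mt-Co1 and mt-Nd4 were at 1.03 and 0.985. The immediate early list had a median of -0.13 (0.10) with 14 of 20 lower, but with clusters weighted alike the median was 0.23 (percentile 100) and without clusters of under 20 cells 0.035. Of its members, Fosb and Jund had ratios of 0.731 and 0.736, and Ier3 and the chaperone Hspa8, whose 3' sequence is 71.5% shared, 1.14 and 1.35.

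Medians of the other lists lay inside the random range in the aorta. Inflammatory activation stood at 0.18, but lay outside the range in 9 of 22 settings, with medians from -0.21 to 0.42. In it 7 of 13 members were higher, with Irf1, an interferon regulatory factor, at a ratio of 0.729 (a log2 ratio of 0.093 at equal depth). Endothelial-to-mesenchymal transition stood at -0.05; within it Acta2, smooth muscle actin, was 1.84-fold higher with 31.0% of the knockout UMIs in 1 cell, higher in 3 of 6 clusters and at log2 ratios of -0.089 as a mean of per-cell CPM and -0.013 at equal depth, and Cyr61, a matricellular protein, had a ratio of 0.729. The medians were -0.02 for endothelial identity, 0.03 for arterial genes, -0.11 for general capillary, -0.01 for aerocyte, 0.02 for 72 nuclear oxidative phosphorylation genes, 0.19 for glycolysis, 0.10 for antioxidant genes and -0.11 for heme and iron handling. They were 0.02 for the Notch pathway, 0.19 for the VEGF response, 0.07 for shear responsive genes, 0.14 for the unfolded protein response, -0.11 for cell cycle, 0.13 for cell junctions, 0.10 for hypoxia and 0.15 for genes near Pou5f1. Only 2 pluripotency genes and 1 gene of cholesterol synthesis were measured. Klf2 and Klf4, transcription factors induced by laminar flow, had ratios of 1.26 (1.20 to 1.34) and 1.12 (1.00 to 1.25), and Hmox1, heme oxygenase 1, a ratio of 1.62 (0.687 to 4.66).

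Transcripts of other cell types differed between the same endothelial-like cells. Fibroblast markers summed to 727 CPM in the wild-type and 1564 CPM in the knockout aorta, and the 5 measured ones had a median log2 ratio of 0.48 (percentile 99.6). Of these 5, 3 were higher and 2 lower. The fibroblast marker Dcn in clusters 2, 4 and 8 alone held 2747 of the 5968 fibroblast marker UMIs of the knockout library, so the sum is not a general rise. Smooth muscle markers summed to 550 and 816 CPM, macrophage markers to 34.8 and 106 CPM and erythroid markers to 3107 and 237 CPM. Clusters 1 and 7 are led against all other cells by Krt18 and Mfap5, markers of other classes, and by none of their own. Without them 28 genes were at least 2-fold higher and 46 lower, the medians of the venous and matrix lists were -0.09 and 0.03, and Klf2 and Klf4 had log2 ratios of -0.05 and -0.14.

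In the lung, knockout endothelial-like cells held more transcripts of MHC class II genes and fewer of Lpin2, Fabp4 and Gmfg. Cd74 stood at 698 CPM in the knockout and 153 CPM in the wild-type library, 4.57-fold higher (3.89 to 5.40), though its log2 ratio was only 0.62 with cells as deposited. H2-DMb1, which helps load peptides, was 6.25-fold higher (3.85 to 10.6), H2-Aa (chromosome 17, 34282744 to 34287823) 3.47-fold (2.59 to 4.70), H2-Eb1 3.40-fold and H2-Ab1 2.25-fold. Lpin2, a phosphatidate phosphatase of lipid synthesis (chromosome 17, 71182560 to 71249817), was 3.68-fold lower (2.71 to 5.10), at 56.6 against 208 CPM, and lower in all 5 clusters; it is also among the genes that lead cluster 2. Of 3347 genes, 14 were at least 2-fold higher and 7 at least 2-fold lower, while 95.5% lay within 1.5-fold.

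Cd74 was not evenly spread over the lung clusters. In the knockout library it stood at 647, 1053, 829 and 1124 CPM in clusters 1 to 4, against 111, 188, 481 and 138 CPM in the wild-type library. Cluster 5, led by the aerocyte genes Fibin, Ednrb and Car4, held 10.2 and 6.4 CPM.

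**Figure D2:**
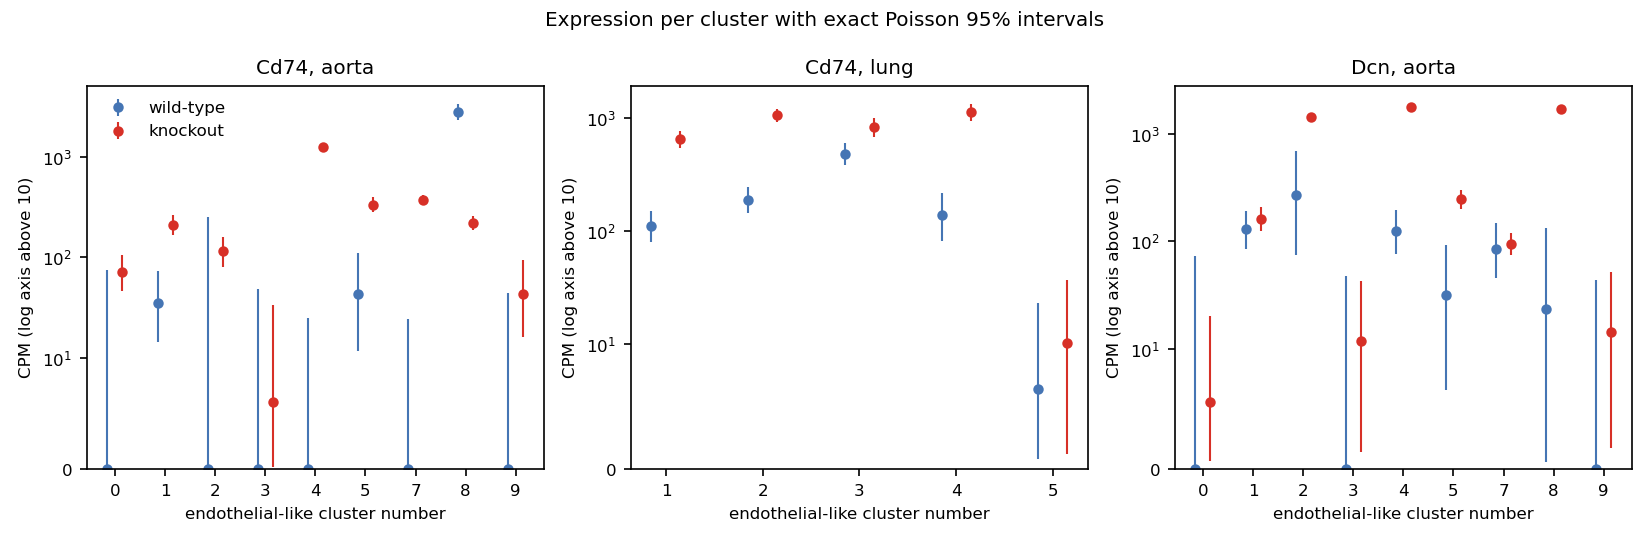
CPM per endothelial-like cluster (log axis above 10, linear below) of Cd74 in aorta and lung and of the fibroblast marker Dcn in the aorta, wild-type in blue and knockout in red, with exact Poisson 95% intervals. Cd74 in the lung was low in cluster 5 of both libraries (6.4 and 10.2 CPM); its high wild-type value in aortic cluster 8 comes from 1 of 10 cells, and Dcn stood at 126 and 1768 CPM in aortic cluster 4 of the wild-type and knockout libraries.

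The remaining genes ranked highest in the lung had varied roles. H2-Q7 and H2-Q6 were 2.24-fold (2.03 to 2.48) and 1.98-fold higher, in 5 of 5 clusters each. Npr3, the clearance receptor of natriuretic peptides, stood at 169 against 59.6 CPM, and Pde4b, a phosphodiesterase that breaks down cAMP, at 225 against 104 CPM. Serpina3g, a protease inhibitor, was 2.60-fold higher, the zinc finger gene Zfp697 2.58-fold (in 2 of 4 clusters) and the inducible heat shock gene Hspa1b 2.31-fold. On the lower side, Fabp4, a fatty acid carrier of capillaries, stood at 47.4 against 173 CPM (28.3% and 29.3% of the wild-type and knockout UMIs in 1 cell each; ratio 0.270 without these), Gmfg, a regulator of branched actin, at 191 against 410 CPM in 5 of 5 clusters, and Cd200, an inhibitory ligand for myeloid cells, at 1386 against 2112 CPM in 5 of 5 clusters. Tcn2, the transcobalamin that carries vitamin B12, had a ratio of 0.682, Esm1, a proteoglycan of angiogenic endothelium, 0.452 (0.381 without the highest cells), the peptidylprolyl isomerase-like gene Ppil2 0.479, Ccdc28b 0.548, the metallothionein Mt1 0.564 (0.619 without the highest cells, but a log2 ratio of 0.48 without the cluster led by immediate early genes), Ypel3 0.608 and Cirbp, a cold-inducible RNA-binding protein, 0.614.

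Of the 28 lists with a median in the lung, 8 lay outside the random range. MHC class II had a median of 1.80 (percentile 100; 0.66 with cells as deposited) with 5 of 5 members higher, and MHC class I 0.27 (100) with 11 of 14 higher; H2-T22 and H2-T23 again had ratios below 1, at 0.824 and 0.852. The unfolded protein response had a median of 0.38 (100) with 11 of 12 members higher, among them Manf, a stress-induced trophic factor of the endoplasmic reticulum, at 201 against 131 CPM in 5 of 5 clusters and the transcription factor Ddit3 at 1.51-fold. Atf4 had a ratio of 1.02, and the chaperone Dnajb9 0.802. The venous list had a median of 0.23 (99.1) with 8 of 10 higher, but -0.040 with clusters weighted alike; Lrg1, a glycoprotein of TGF-beta signalling, was 1.74-fold (higher in 2 of 5 clusters) and the noradrenaline transporter Slc6a2 1.64-fold higher, and both lead cluster 4, while Cpe and Ptgs1 had ratios of 0.780 and 0.838.

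Smaller shifts above the random range were seen for Notch, shear responsive and Pou5f1-neighbouring genes. The Notch list had a median of 0.21 (98.4) with 6 of 9 higher, but lay outside the range in only 11 of 22 settings and was -0.072 with no filter on CPM. Its target genes Hes1, at 1225 against 918 CPM, and Nrarp were 1.33- and 1.43-fold higher, and the ligand Dll4 and the glycosyltransferase Mfng had ratios of 0.923 and 0.897. The shear responsive list had a median of 0.14 (98.8) with 10 of 15 higher, but -0.0037 with cells as deposited. Thbd, the anticoagulant thrombomodulin, was 1.53-fold higher (1.41 to 1.67) in 5 of 5 clusters, while Tfpi had a ratio of 0.710. Genes near Pou5f1, 7 of which are also in the MHC class I list, had a median of 0.16 (99.7) with 14 of 22 higher, but -0.0022 at equal depth, and Ddah2, which degrades an inhibitor of nitric oxide synthase, at a ratio of 0.817. Below the range, lipid efflux and ABC transporters had a median of -0.25 (0.72) with 5 of 7 lower. Abcg2 (chromosome 6, 58584523 to 58695676) had a ratio of 0.604 (0.475 to 0.763) and was lower in 4 of 5 clusters, Mylip stood at 132 against 211 CPM and was lower in 5 of 5, and Scarb1 and Nr1h2 had ratios of 1.19 and 1.16.

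**Figure D3:**
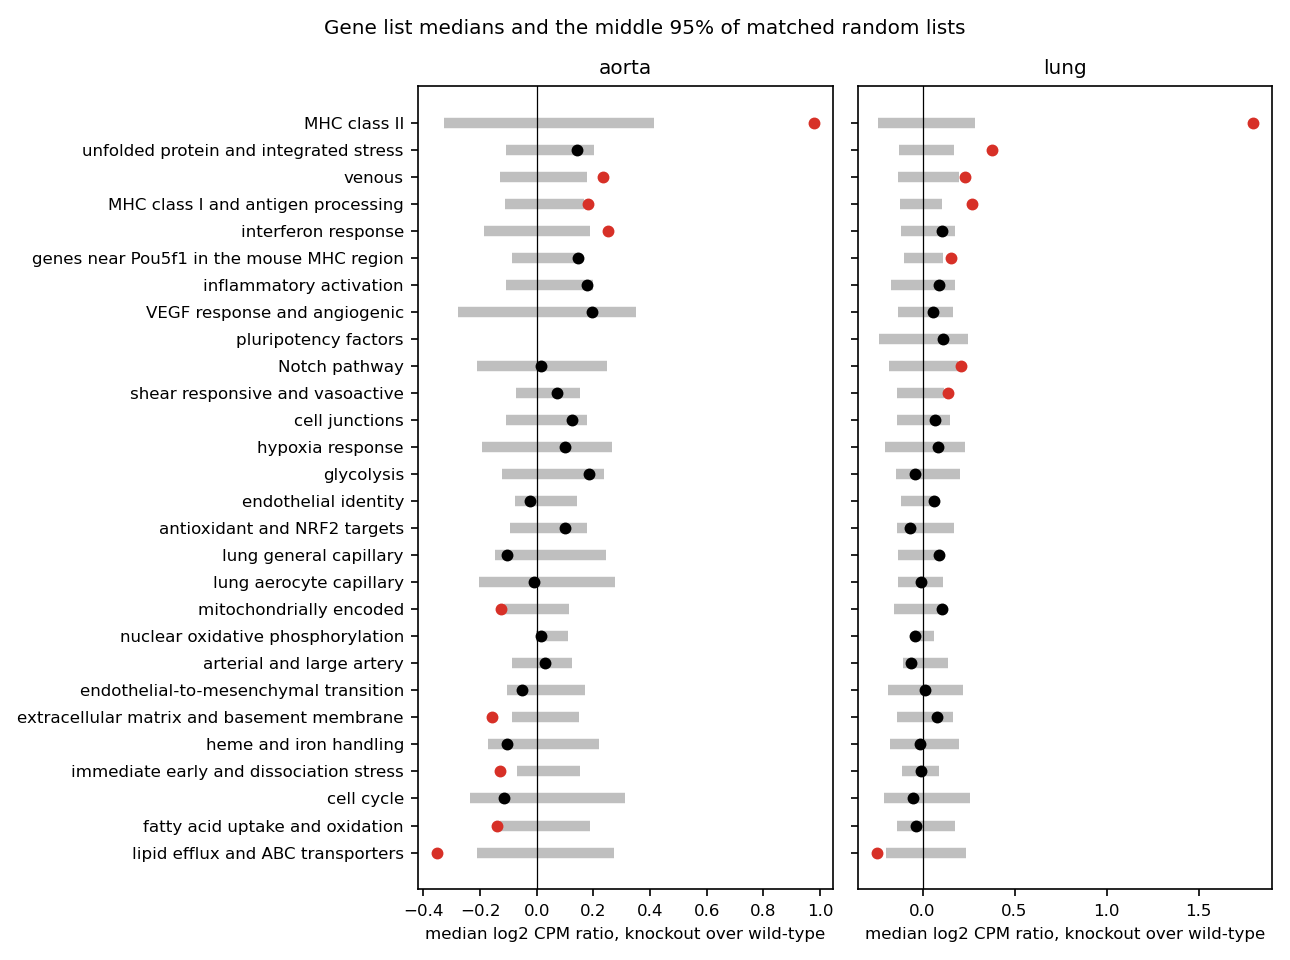
Median log2 CPM ratio (knockout over wild-type) of each gene list with at least 3 measured members in the aorta (left) and lung (right), with gray bars for the middle 95% of 10000 matched random lists and red points for medians outside it. MHC class II stands at 0.98 and 1.80 and lipid efflux at -0.35 and -0.25.

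The other lung lists lay inside the random range. Their medians were 0.09 for inflammatory activation, where Vcam1 was 1.34-fold higher (a log2 ratio of -0.0021 with clusters weighted alike) and Socs3, a suppressor of cytokine signalling, and Nfkbiz had ratios of 0.853 and 0.858 (Socs3 at a log2 ratio of 0.36 without the cluster led by immediate early genes), and 0.02 for endothelial-to-mesenchymal transition, where Ccn2 and Ccn1, the newer symbols of Ctgf and Cyr61, had ratios of 1.37 and 0.882, against 0.425 and 0.729 in the aorta. Tagln, a smooth muscle gene of that list, had a ratio of 0.141, but 86.6% of its wild-type UMIs came from 1 cell and the ratio without the highest cells was 0.790. Medians were 0.06 for endothelial identity, -0.06 for arterial genes, 0.09 for general capillary, -0.01 for aerocyte, 0.11 for 3 pluripotency genes, 0.11 for mitochondrially encoded (outside the range in 10 of 22 settings) and -0.04 for nuclear oxidative phosphorylation genes. They were -0.04 for glycolysis, -0.03 for fatty acids, -0.07 for antioxidant genes, -0.01 for heme and iron, 0.06 for VEGF, 0.11 for interferon, -0.01 for immediate early genes, -0.05 for cell cycle, 0.08 for matrix, 0.07 for junctions and 0.08 for hypoxia. Klf4 had a ratio of 1.29 (1.18 to 1.40) and was higher in 5 of 5 clusters, Klf2 1.01 (0.964 to 1.06) and Hmox1 0.622 (0.172 to 1.90). In the same cells airway markers summed to 492 CPM in the wild-type and 829 CPM in the knockout lung. The airway marker Scgb1a1 held 43 of 635 of these UMIs in the wild-type and 375 of 718 in the knockout library. The higher airway sum rests on this gene. Macrophage markers summed to 146 and 186 CPM, smooth muscle markers to 239 and 124 CPM, fibroblast markers to 41.0 and 21.9 CPM and erythroid markers to 48.0 and 102 CPM.

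To see whether both tissues moved alike, the ratios of 2508 genes measured in both under the same symbol were compared. Several MHC genes, but not H2-T22 and H2-T23, and a few others were higher in both knockout libraries, and across all genes the ratios were weakly related. The Spearman correlation was 0.14 and the Pearson correlation 0.16 across genes, which are not independent replicates. At least 1.5-fold higher in both tissues were 9 genes, where independent lists would share 1.21, among them H2-Aa, H2-Ab1, Cd74, H2-Q6, H2-Q7, Tgm2, a transglutaminase, Emp1 and Glo1, the glyoxalase that detoxifies methylglyoxal. At least 1.5-fold lower in both were 2 genes, where independent lists would share 0.724: the sulfotransferase Sult1a1, with log2 ratios of -0.94 in the aorta and -0.62 in the lung, and Cirbp, with -0.81 and -0.70. Glo1 had log2 ratios of 0.78 and 0.89, Tgm2 0.60 and 0.70 and Emp1 0.60 and 0.74. At least Glo1, H2-Aa, H2-Q6 and H2-Q7 lie on chromosome 17 within 10 Mb of Pou5f1. Variants near the altered gene could therefore bear on this overlap. The difference between tissues was not tested, and the genes of this overlap were named after their values were seen. The labels give 2 wild-type and 3 knockout mice for both tissues. If these are the same mice, differences between them would appear in both tissues, so the count for independent lists is only a reference.

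**Figure D4:**
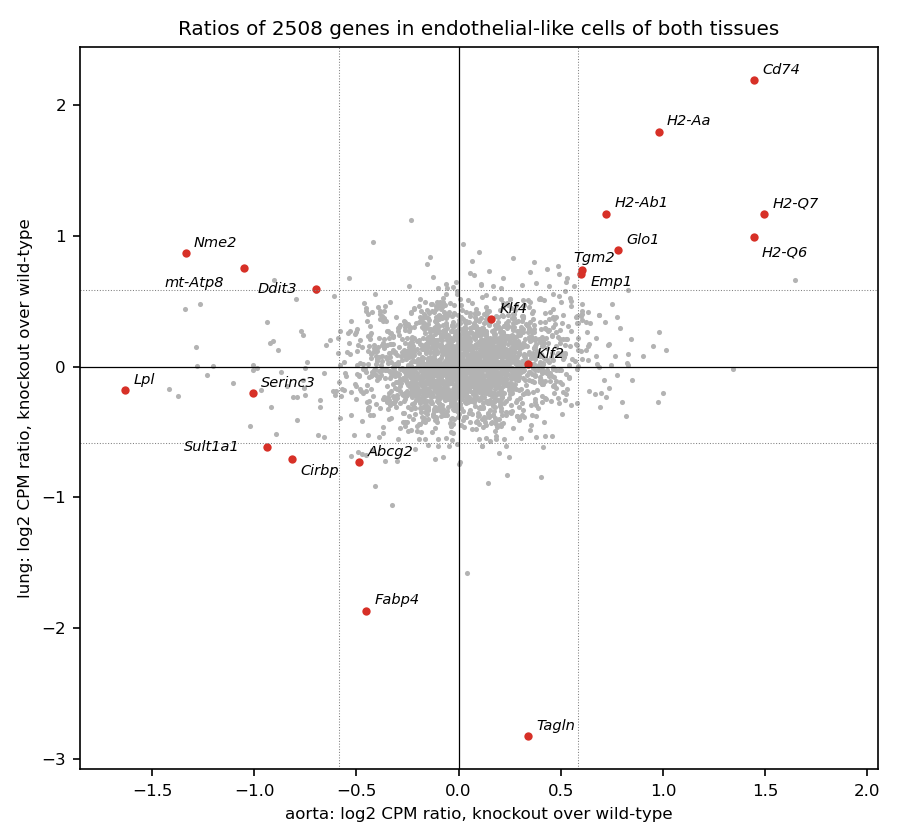
Each point is 1 of 2508 genes, with its log2 CPM ratio of knockout over wild-type in the aorta (x axis) and lung (y axis); dotted lines mark 1.5-fold and named genes are red. Cd74 (1.45 and 2.19) and H2-Q7 (1.49 and 1.17) lie at the upper right and Fabp4 at the bottom with -1.87 in the lung; Tagln rests on 1 wild-type lung cell.

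Aortic and lung endothelial-like cells of the wild-type mice differed in many genes that mark their vascular beds. Cytl1, a cytokine-like secreted protein, stood at 16681 CPM in the aorta and 239 CPM in the lung, a 69.9-fold difference. Sfrp1, a Wnt antagonist, stood at 480 and 2.33 CPM, Nupr1, a stress-induced chromatin protein, at 553 and 3.89 CPM, and Ephx2, a soluble epoxide hydrolase, Gkn3 and Klk10 at 298, 270.2 and 261 CPM against 0.777 CPM each. Adh7, an alcohol dehydrogenase, and the noncoding RNA Meg3 had 0 UMIs in the lung and were at least 145- and at least 140-fold higher in the aorta, against a limit of 3 counts. In the other direction Foxf1, a lung mesoderm transcription factor, and Sema3c had 0 UMIs in the aorta and were at least 280- and at least 232-fold higher in the lung. Fibin and Car2, a carbonic anhydrase, also had 0 UMIs in the aorta, against 606 and 177 CPM. Hpgd, which inactivates prostaglandins, stood at 3461 against 9.32 CPM, Tmem100 at 1976 against 10.5 CPM, Prx at 432 against 1.16 CPM and the mitochondrial carrier Ucp2 at 708 against 9.32 CPM.

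Of 3236 genes, 280 were at least 2-fold higher and 523 at least 2-fold lower in the wild-type aorta than in the lung. In the knockout pair 274 of 3268 were higher and 565 lower, 214 and 433 of them the same genes, and across 3057 genes the tissue ratios of both genotypes had a Spearman correlation of 0.89. Medians above the random range were 3.50 for extracellular matrix, 2.5 for arterial genes, 1.48 for endothelial-to-mesenchymal transition, 0.58 for venous genes and 0.16 for nuclear oxidative phosphorylation, where 56 of 72 genes were higher. Below it were general capillary (-3.85) and aerocyte genes (-3.65, 13 of 13 lower), VEGF response (-1.90, 10 of 10 lower), cell cycle (-1.91), hypoxia (-1.24), MHC class I (-0.98, 13 of 14 lower), endothelial identity (-0.84), interferon (-0.83), junctions (-0.65), genes near Pou5f1 (-0.54) and immediate early genes (-0.53). Lists inside the range were pluripotency (-1.02), Notch (-0.70), lipid efflux (-0.48), shear responsive (-0.15), fatty acids (0.08), unfolded protein response (0.09), antioxidant (0.14), inflammatory activation (0.15), glycolysis (0.25), heme and iron (0.34) and mitochondrially encoded genes (0.43). Tissue and library cannot be separated here, and the aortic matrices list genes by symbol while the lung matrices list identifiers.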

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

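The genes and values in this part were chosen after the results were seen, and no difference in it was tested. Several results point opposite ways in aorta and lung. Nme2 had log2 knockout over wild-type ratios of -1.34 in the aorta and 0.87 in the lung, mt-Atp8 -1.05 and 0.75, the ribosomal pseudogene Rpl10-ps3 -0.90 and 0.66 and the stress transcription factor Ddit3 -0.70 and 0.60. The list of mitochondrially encoded transcripts had medians of -0.13 and 0.11, below the random range in the aorta and inside it in the lung, though above it there in 10 of 22 settings, and the extracellular matrix list -0.16 and 0.079, below and inside. With 1 library per group the difference between tissues was not tested.

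Scgb1a1, a secretory protein of airway club cells, stood out in the knockout lung, where 1 barcode held 28398 of the 31690 UMIs of the library; the wild-type lung held 974. At least 1 UMI of it was found in 269 of 529 knockout and 34 of 800 wild-type barcodes. Endothelial-like cells stood at 433 and 33.3 CPM. The cause was not tested.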

How the results depend on the processing

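Alternatives called added here were chosen after the results were seen. No paired analysis was possible because each group is 1 library and the mice in it are not told apart. Of the alternative values, 97 of 133 for counts, shares and the correlation stayed close to the first value and 36 moved; for lists 1131 stayed, 57 moved and 13 reversed, and for named genes 1859 stayed, 192 moved and 15 reversed. A reversal is a change of sign in a list first outside the random range or a gene whose first interval left out a ratio of 1, and the cause was not tested. Other changes of sign are not counted as reversals. Lists with fewer than 3 members left under an alternative gave no value, as MHC class II in the aorta with clusters weighted alike.

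Aortic genes at least 2-fold higher numbered 20 without mitochondrial and ribosomal genes, 8 with the marker gate, 21 thinned to equal depth, 22 with the stricter cell filter, 28 without clusters led by another class (added), and 51, 639 and 8 with mean CPM of at least 20, no filter on CPM and mean CPM of at least 100. Genes at least 2-fold lower numbered 46 without clusters led by another class, 16 with the highest cell of each gene left out (added), 72, 1000 and 17 with the same CPM filters, and 17 without genes with shared 3' sequence (added). In the lung, 35 were higher thinned to equal depth, 22 with cells as deposited, and 53, 544 and 8 with the CPM filters; 18 were lower with all kept cells, 16 thinned, and 43, 627 and 3 with the CPM filters. The correlation between tissues was 0.0724 with the mean of per-cell CPM, 0.0859 thinned to equal depth, 0.0989 without clusters led by another class and 0.0908 without immediate early clusters (added).

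The endothelial-like share of the knockout aorta was 90.5% with cells as deposited, 88.6% with the stricter cell filter, 88.6% with doublets kept and 88.3% at Leiden resolution 2. With cells as deposited it was 92.7% in the wild-type and 96.4% in the knockout lung, the latter 94.3% at Leiden resolution 2 and 93.7% with joint clustering.

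Reversed aortic list medians were, for venous genes, -0.013 with clusters weighted alike, -0.087 without clusters led by another class, -0.095 with mean CPM of at least 20 and -0.095 with no filter on CPM; for immediate early genes 0.23 with clusters weighted alike (percentile 100, above the random range) and 0.035 without clusters of under 20 cells (added); for matrix 0.034 without clusters led by another class; for MHC class II -0.24 without immediate early clusters; and for interferon -0.060 with mean CPM of at least 100. Reversed lung medians were -0.040 for venous genes with clusters weighted alike, -0.0022 for genes near Pou5f1 thinned to equal depth, -0.0037 for shear responsive genes with cells as deposited and -0.072 for Notch with no filter on CPM. MHC class I lay outside the random range in 20 of 22 settings in the aorta and 22 of 22 in the lung, MHC class II in 14 of 17 and 22 of 22, and the lung unfolded protein response in 22 of 22. For other lists it was 11 of 22 for Notch in the lung, 14 for shear responsive genes in the lung and venous genes in the aorta, 15 for fatty acids, 16 for lipid efflux and 17 for mitochondrially encoded genes in the aorta, 18 for matrix in the aorta and for lipid efflux and genes near Pou5f1 in the lung, and 19 for venous genes in the lung and immediate early and interferon genes in the aorta. Of lists first inside the range, mitochondrially encoded genes in the lung lay outside in 10 and inflammatory activation in the aorta in 9 of 22, and no other list in more than 6. Such lists also changed sign in the aorta, as inflammatory activation (down to -0.21), VEGF (-0.20), arterial genes (-0.15), hypoxia (-0.14), endothelial-to-mesenchymal transition (up to 0.29) and cell cycle (0.44). Cd74 and MHC class II in the lung fell to log2 values of 0.62 and 0.66 with cells as deposited. In that setting the endothelial-like share rose from 91.3% to 96.4% in the knockout and from 89.9% to 92.7% in the wild-type lung. The class of cells compared therefore changed too. The aortic MHC class II value of -0.24 comes from a setting that keeps cluster 8, where 1 wild-type cell held 117 Cd74 UMIs.

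Reversed log2 ratios in the aorta were Acta2 -0.089 (mean of per-cell CPM) and -0.013 (thinned to equal depth), H2-Aa -0.24 and H2-Ab1 -0.34 (without immediate early clusters), Irf1 0.093 (thinned), Klf2 -0.046 and Klf4 -0.14 (without clusters led by another class), Scarb1 0.027 (stricter cell filter), Selp -0.19 (clusters weighted alike) and mt-Co1 -0.031 (clusters weighted alike), -0.031 (cells as deposited) and -0.0061 (without immediate early clusters). In the lung they were Mt1 0.48 and Socs3 0.36 (without immediate early clusters) and Vcam1 -0.0021 (clusters weighted alike). Genes whose first interval included a ratio of 1 changed sign too, among them Abca1 (-0.49) and Ephb4 (0.099) in the aorta and Dll4 (0.31), Ccn1 (0.12) and Atf4 (-0.097) in the lung.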

Other observations

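All patterns in this part, and the tests of genes near Pou5f1, of cluster shares, of free RNA and of doublets with fibroblasts, were chosen after the results were seen. Lymphatic endothelial-like cells, 40 wild-type and 192 knockout in the aorta, were not part of the comparisons and their genes were picked by value. In the knockout aorta Plat, tissue plasminogen activator, stood at 502 against 70.8 CPM (7.09-fold, 3.20 to 19.5) and the endothelin receptor Ednrb at 427 against 59.0 CPM. Cebpb, a transcription factor, had a ratio of 0.296 (0.188 to 0.471) and Tgfbi, a matrix protein, 0.365 (0.251 to 0.534). H2-Q7 stood at 185 against 35.4 CPM, and Abcg2 had a ratio of 0.451.

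In the lung, with 42 wild-type and 18 knockout lymphatic-like cells, Spp1, the matrix phosphoprotein osteopontin, stood at 1017 against 105 CPM (9.73-fold, 4.81 to 21.7) and Angpt2, a ligand of the Tie receptor, at 544 against 167 CPM. Gpx3, a secreted glutathione peroxidase, had a ratio of 0.148. Abcg2 had a ratio of 1.23 (0.556 to 2.60) and H2-Q7 of 1.66 (0.689 to 3.86). Cd74 had ratios of 2.33 (0.338 to 100) in the aortic and 1.13 (0.0192 to 21.7) in the lung lymphatic-like cells.

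Most MHC genes were higher in both knockout libraries, although H2-T22 and H2-T23 were lower in both; the pattern was found and tested in the same data. Cells holding a UMI of Ptprc, Tyrobp, Fcer1g, Lyz2 or Cd79a were left out. Cd74 then had a ratio of 4.66 (3.95 to 5.50) in the lung and 1.92 (1.60 to 2.32) in the aorta. In the lung this argues against doublets with antigen-presenting cells as the only source. There 2 of 174 Cd74-positive and 3 of 277 Cd74-negative knockout endothelial-like cells held such a UMI. In the aorta the filter kept a wild-type cell with 117 Cd74 UMIs. It can therefore miss such cells and cannot decide there. The filter cannot decide on free RNA, since a cell with free Cd74 RNA need not hold a UMI of those genes. In the knockout lung Cd74 stood at 10.2 CPM in cluster 5, against 647 to 1124 CPM in clusters 1 to 4. In the knockout aorta it ranged from 5.98 CPM in cluster 3 to 1262 CPM in cluster 4. These values argue against free RNA spread evenly over cells as the only source of Cd74. They do not extend to H2-Q7, which stood at 778 CPM in cluster 5 of the knockout lung. In the aorta 117 of the 128 wild-type Cd74 UMIs left lie in 1 cell. With clusters weighted alike the MHC class II median was 1.72 in the lung, which argues against cluster shares there. In the aorta the log2 ratio of Cd74 was 4.88 with clusters weighted alike and 5.13 without clusters of under 20 cells. Both settings drop cluster 8, which holds that cell, whereas the 0.18 without immediate early clusters keeps it. Within aortic clusters 1, 4, 5 and 7, Cd74 stood at 210, 1262, 333 and 372 CPM in the knockout library. In the wild-type library it stood at 35.2, 0, 42.6 and 0 CPM there (7, 0, 4 and 0 UMIs). Only cluster 8 went the other way, through that cell. These values argue against cluster shares as the whole source of the Cd74 difference in the aorta. For the MHC genes of chromosome 17, variants near Pou5f1 that came with the altered allele stay open. This does not extend to Cd74 on chromosome 18, which was not tested. Of other genes within 10 Mb of Pou5f1, 9.09% (3.41 to 18.7) were at least 1.5-fold apart in the lung, against 4.19% of all other genes. In the aorta it was 10.2% against 5.50%. Among these neighbours only Glo1 was apart the same way in both tissues. A higher level of MHC genes in endothelial cells without Oct4 is a hypothesis that protein staining in several mice per genotype could test. Mouse, library and genotype cannot be separated here.

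Some genes with shared 3' sequence were lower in the knockout aorta. The 18 genes with at least 90% shared had a median log2 ratio of -0.33, below the middle 95% of random lists (-0.10 to 0.14), with 7 at least 1.5-fold lower and 1 higher, while all 91 genes with at least 50% shared had a median of -0.024. The former is consistent with reads of near-identical copies being counted differently in these libraries, but the 18 include genes that prompted the pattern; this test replaced an earlier one, the share of shared-sequence genes among lower genes (10 of 26 with and 7 of 23 without haemoglobin genes), because that one restated the pattern. With clusters weighted alike the 7 shared-sequence genes at least 2-fold lower had a median of -1.37, which argues against cluster shares. Counting both libraries again from reads with the same annotation could test this hypothesis.

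Dcn, the small proteoglycan decorin and a fibroblast marker, stood at 1768 CPM in cluster 4 of the knockout aorta. Its level there was 314 times that of cluster 0 (86.7 to 2596), which argues against free RNA spread evenly over cells. Clusters 2, 4 and 8 held 4.59 collagen UMIs per 100 Dcn UMIs (3.81 to 5.48), against 35.5 (30.3 to 41.6) in the macrophage-like cluster that also holds fibroblast genes, which argues against cells like those; Lum, another fibroblast marker, went with Dcn there (241, 237 and 219.9 CPM, and 0 in every wild-type cluster), so fibroblasts with little collagen stay open. Within cluster 4, picked for its high level, the knockout over wild-type ratio was 14.0 (8.92 to 23.3), which argues against cluster shares as the whole cause. Of its 159 knockout cells, 44 held the 1178 UMIs. In cluster 5 Dcn stood at 246 against 32.0 CPM. In clusters 1 and 7 the libraries were close, at 162 against 131 and 95.1 against 85.9 CPM. Whether endothelial cells or a subset of mice made this RNA was not tested, and staining for decorin in traced cells could test it.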
